A study of Aliivibrio fischeri ES114 with 23 samples.

How the data were processed

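RNA from Vibrio fischeri strain ES114 was measured by RNA-seq in 23 libraries. Of these, 9 form the main experiment, with 3 libraries each from growth in SWT (a seawater-based tryptone broth that contains glycerol), from cells held in sterile artificial seawater (planktonic), and from bacteria expelled by the squid Euprymna scolopes (vented). The other 14 test library preparation at low RNA input: 3 undepleted and 8 ribodepleted libraries at 15 PCR cycles, and 3 ribodepleted libraries at 17 cycles. Groups, replicate numbers, RNA inputs and cycle numbers were taken from the labels. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

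The authors deposited read counts per annotated gene, 1 count table for the main experiment and 1 for the low-input test. Per the labels' protocols, ribosomal RNA of both bacterium and squid was removed with a commercial kit, except in the undepleted libraries, and single-end reads of 100 bp were sequenced. Trimmomatic 0.33, BWA 0.6.2, SAMtools and HTSeq 0.6.1p1 are named in the submitters' processing notes. The genome build and the strand setting of the counting are not given in the sources used here. Reads of overlapping genes, antisense pairs and near-identical copies such as the flagellin genes therefore cannot be assigned with certainty. The counts were used as deposited. The 5 special entries of the counter that name no gene, which include reads that did not align, were kept out of library sizes and tests. Reads that did not align made up 2.67% ± 0.891 (SD, n = 3) of the reads in SWT, 3.84% ± 1.86 in planktonic and 74.9% ± 14.0 in vented libraries. Aligned reads assigned to neither a protein-coding gene nor an rRNA gene made up 12.9% ± 0.284, 27.1% ± 3.07 and 23.7% ± 4.40 of aligned reads. Counts of 37 rRNA genes were used only for the rRNA share. After removal of 1 duplicated entry, 3815 protein-coding genes (CDS) remained. Further, 1 column whose name matches no sample's label was not used. Its counts are those of SWT replicate 3, so that library may also belong to the low-input test.

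Locus tags were paired with gene symbols through the RefSeq table of assembly ASM1180v1, used for names and for which genes neighbour each other. It held 3653 of the loci, and 1266 carried a symbol. A gene without a symbol is named by its locus tag and the product given in the deposited tables.

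Expression was compared with the quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) on CDS counts, with TMM scaling and edgeR's default low-count filter by group. All 9 main libraries entered one fit with group as the only term and 6 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Fold changes are fitted log2 values with their standard error (SE). Levels are CPM (read counts scaled to a common library size) with TMM scaling, as mean ± SD over 3 libraries. Of 45 gene lists, 44 with at least 4 measured members were tested (1 had no member) with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of each comparison. Genes distinct in vented passed the test against both other groups in the same direction. In the low-input test, ribodepletion was compared in the 4 libraries at 1000 and 500 ng, cycle number in the 6 libraries at 5, 2.5 and 1 ng with input as a factor, and RNA input as a slope on log2 input in the 8 ribodepleted libraries at 15 cycles. Relations of library measures with log10 input and the difference in rRNA share were tested with exact two-sided permutation tests. For detection, libraries were thinned at random to 907516 CDS reads and a gene was counted at 10 or more reads. Correlations between libraries are Pearson's r across genes, on edgeR's log2 CPM for the main libraries and on log2(CPM + 1) for the low-input and thinned libraries. Genes are not independent replicates.

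The tests, their samples, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. For each main comparison the rule took the 8 largest rises and 8 largest falls past the threshold, with a mean of at least 20 CPM in the higher group and no overlap between the libraries of both groups. To these it added up to 2 rising and 2 falling members of each list that passed, all luminescence genes, and 8 genes per direction distinct in vented. For the low-input comparisons it took 5 genes per direction. It yielded 65 genes for vented against planktonic, 77 for vented against SWT and 44 for planktonic against SWT. A gene named outside the rule was chosen after its values were seen, and is marked so.

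The alternatives were other scaling (RLE, library totals), DESeq2 1.42.0, other low-count filters, a replicate block, only the groups compared, removal of the 20 most abundant genes, a fold minimum, and each library left out in turn. In each main comparison only libraries of the groups compared were left out. For genes distinct in vented each main library was. For the lists they were an estimated correlation and the rotation test fry. For the profile against input they were another pseudocount than 1, an expression minimum and rank correlation. Leaving out each library in the ribodepletion test, and thinning all libraries for the profile, were added after the data were seen. Whether the replicate numbers of the labels pair libraries was read from correlations across genes of the deviations from each group's mean. They were 0.132, 0.143 and 0.182 for same-numbered planktonic and vented libraries (differently numbered ones at most 0.0891). Between SWT and either group they were -0.102 to 0.00248 for the same number. Of different numbers, planktonic replicate 2 also reached 0.143 with SWT replicate 1, and -0.136 with SWT replicate 3. The numbers may thus pair planktonic with vented libraries, which no label states, and show no pairing of SWT with either. A pairing was not tested. For vented against planktonic the fit with the block, over all 9 libraries, is given beside the other.

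The CDS depth ran from 687894 to 16880303 reads in the main libraries and from 907516 to 14982254 in the low-input libraries. Shares for single libraries carry 95% Wilson intervals, which cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The scripts were tested on simulated counts with known changes. For vented against planktonic, over 3743 simulated genes, 2.99% of 2-fold, 35.8% of 4-fold and 84.8% of 16-fold changes were recovered, with 4 false calls among 86. For vented against SWT (3743 genes) the shares were 2.99%, 35.8% and 89.4%, with 2 false calls among 87, and for planktonic against SWT (3747 genes) 0%, 35.8% and 97.0%, with 1 false call among 89. In the low-input test, 2-fold changes were recovered at 91.0% for ribodepletion (3583 genes, 12 false calls among 206), 37.3% for cycle number (3228 genes, 7 among 136) and 53.7% for RNA input (2891 genes, over the whole input range, 4 among 157). Figures were drawn with matplotlib 3.10.9.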

Results

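The series asked which transcriptional signals of Vibrio fischeri ES114, the light-organ symbiont of the Hawaiian bobtail squid, go with colonization of the host. Transcripts were counted in cells growing in SWT broth at 28 °C to an OD600 of about 0.5, in planktonic cells kept overnight in sterile seawater at about 23 °C, and in bacteria vented by squid. Venting is the daily expulsion of most of the symbionts at first light. Here it followed about 48 h of colonization and 12 h of darkness, and was induced by 15 min of light in batches of 100 animals. Each group had 3 libraries made from 100 ng of total RNA with ribodepletion and 15 PCR cycles. A further 14 libraries addressed how far RNA input, ribodepletion and PCR cycle number change such measurements.

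SWT libraries held 16880303, 15195199 and 4229734 reads in protein-coding genes (CDS; replicates 1 to 3), planktonic libraries 12169855, 13846599 and 16122837, and vented libraries 687894, 3837475 and 7041843. The share of reads that aligned to the V. fischeri genome was 97.3% ± 0.891 (SD, n = 3) in SWT, 96.2% ± 1.86 in planktonic and 25.1% ± 14.0 in vented libraries. Within vented, replicate 1 had 15.2% aligned (95% Wilson interval 15.2 to 15.3), replicate 2 had 19.0% (19.0 to 19.0) and replicate 3 had 41.2% (41.2 to 41.2). Ribosomal RNA made up 0.595% ± 0.136 of CDS plus rRNA reads in SWT, 0.283% ± 0.367 in planktonic and 0.0785% ± 0.0448 in vented libraries. Across genes, replicates 2 and 3 of a group correlated at 0.985 in SWT, 0.985 in planktonic and 0.970 in vented. Replicate 1 stood apart in each group, with correlations of 0.918 and 0.919 in SWT, 0.918 and 0.913 in planktonic, and 0.665 and 0.664 in vented. All pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom of at least 62.7).

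**Figure D1:**
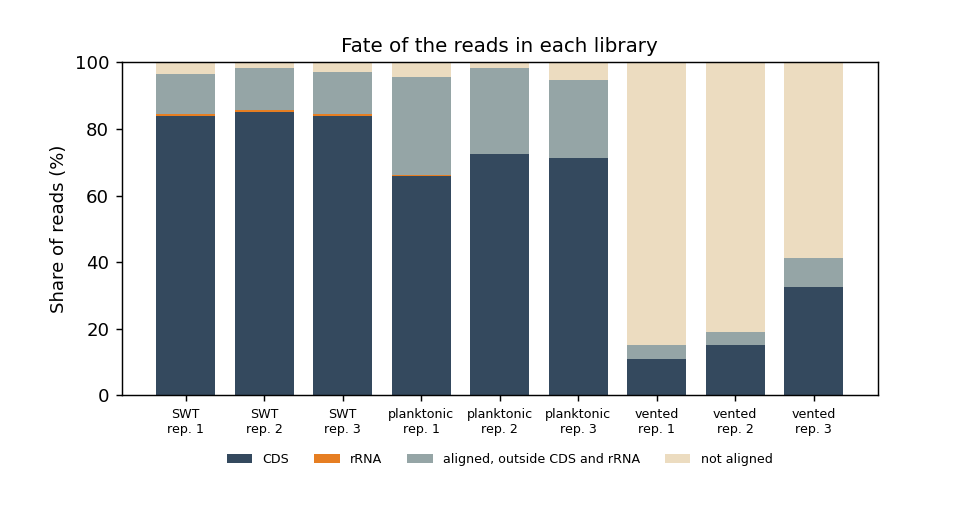
Share of reads in percent (y axis) by fate in each of the 9 main libraries (x axis, 1 bar per library): protein-coding genes (CDS), rRNA genes, aligned elsewhere, and not aligned. The aligned share was 15.2 to 41.2% in vented libraries and at least 94.7% in the others.

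Vented against planktonic cells set the bacteria released by the host beside cells of the same strain in seawater. All 8 measured luminescence genes rose in vented cells, each with all 3 vented libraries above all 3 planktonic and all 3 SWT libraries. The luciferase alpha chain gene luxA (VF_A0921) stood at 57.9 ± 47.7 CPM (SD, n = 3) in planktonic and 3435 ± 2838 CPM in vented cells, a log2 fold change of 5.89 (SE 0.85, adjusted p = 0.00702). The gene for the beta chain (VF_A0920) rose by 6.14 (SE 1.06), that for the autoinducer synthase LuxI (VF_A0924) by 4.97 (SE 0.84), the FMN reductase gene next to that of LuxE (fre_VF_A0918) by 4.57 (SE 0.56) and that for the LuxR family regulator (VF_A0925) by 2.46 (SE 0.43). Without planktonic replicate 3 the adjusted p was 0.0636 for VF_A0919, VF_A0920, VF_A0924 and VF_A0925 and 0.0506 for VF_A0923, and without planktonic replicate 2 it was 0.0504 to 0.0554 for those 4 genes. A pair of neighbouring glutathione S-transferase genes rose too: VF_1082 from 16.9 ± 7.37 to 943 ± 370 CPM (log2 5.80, SE 0.54, adjusted p = 0.000642) and yghU_VF_1083 from 45.2 ± 9.92 to 1451 ± 363 CPM (log2 5.00, SE 0.41, adjusted p = 0.000357).

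**Figure D2:**
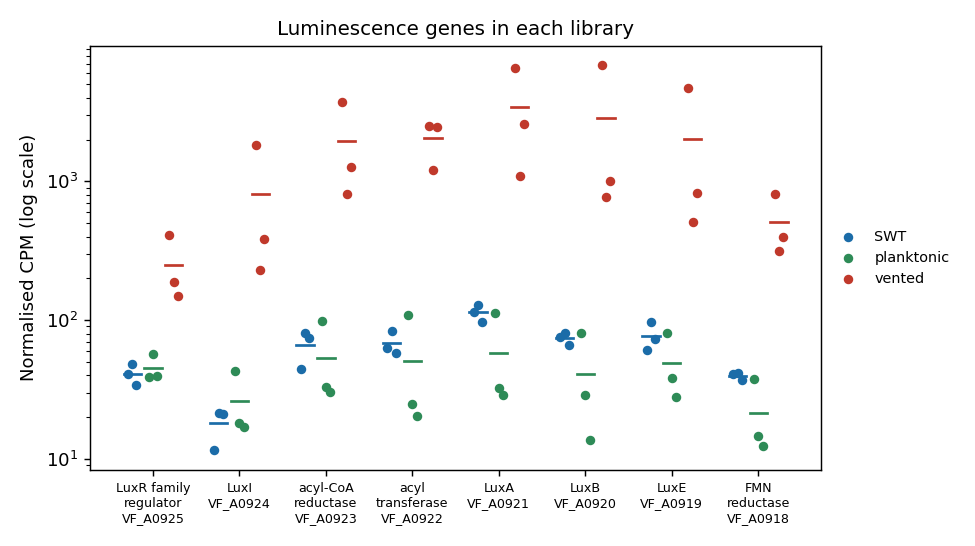
Normalised CPM (y axis, log scale) of the 8 luminescence genes (x axis, by locus number from the LuxR family regulator to the FMN reductase) in SWT, planktonic and vented libraries. Points are libraries and short lines are group means (n = 3). For luxA the means were 113 (SWT), 57.9 (planktonic) and 3435 CPM (vented).

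Among the deepest falls from planktonic to vented cells were genes of uptake. Those of a high-affinity phosphate transporter fell together: the phosphate-binding protein VF_1610 went from 9422 ± 3190 to 164 ± 72.3 CPM (log2 -5.85, SE 0.68, adjusted p = 0.00198), and pstC, pstA_VF_1612 and pstB_VF_1613 fell by 6.14, 5.52 and 5.55 on the log2 scale. The phosphatase VF_A1057 fell by 5.86, the outer membrane porin OmpU2 (VF_A0487) went from 2405 ± 970 to 20.2 ± 3.16 CPM (log2 -6.91, SE 0.68), and the substrate-binding protein VF_A1087 of an ABC transporter from 974 ± 699 to 1.85 ± 0.793 CPM (log2 -9.19, SE 0.74). Of the 16 measured genes on the phosphate starvation list, 5 fell and 2 rose (7 and 3 adjusted over the list alone). The fifth fall was that of the phosphate-binding protein VF_A0555 (log2 -1.68), named after its value was seen. The rises were in the sensor phoR (log2 2.22) and in VF_1986, its neighbour, a further phosphate-binding protein (log2 1.81). Without planktonic replicates 2 or 3 the adjusted p was 0.0543 and 0.0636 for phoR and 0.0959 and 0.0882 for VF_1986, which also reached 0.0651 without vented replicate 2 0.077 with only both groups in the fit and 0.0526 with replicate as a further term in the fit. The list was lower by camera (median log2 -0.63, adjusted p = 0.0055, and 0.552 with an estimated correlation).

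Flagellum and motor, ribosomal protein and ATP synthase genes were lower in vented than in planktonic cells. Of 53 measured flagellum and motor genes, 26 fell and none rose (42 fell adjusted over the list alone), with a list median of -2.24. Among them fliF, the ring protein in the membrane, fell from 1058 ± 580 to 73.8 ± 34.2 CPM (log2 -3.83, SE 0.71) and flaG from 94.7 ± 39.5 to 4.94 ± 4.30 CPM (log2 -4.08, SE 0.72). Of 56 ribosomal protein genes, 21 fell and none rose (32 fell adjusted over the list alone), with a median of -1.50. For example, rpsE fell from 3264 ± 1515 to 254 ± 123 CPM (log2 -3.68, SE 0.57) and rpsD from 3569 ± 1042 to 331 ± 50.0 CPM (log2 -3.43, SE 0.42). Of 7 ATP synthase genes, 5 fell, over all genes and adjusted over the list alone, with atpG at -2.89 (SE 0.54) and atpA at -2.64 (SE 0.52), beside atpD, atpH and atpE, named after their values were seen. The camera test gave adjusted p = 7.39e-18 for flagellum, 2.69e-14 for ribosomal proteins, 2.13e-05 for ATP synthase and 7.95e-14 for luminescence. With an estimated correlation each of these had an adjusted p = 0.552. With replicate as a further term the camera calls stayed, and 12 flagellum and motor, 13 ribosomal protein and 2 ATP synthase genes fell. Chemotaxis genes (1 of 54 rose and 5 fell, 8 and 9 adjusted over the list alone, median 0.21) and aminoacyl-tRNA synthetase genes (median -0.34) did not pass as lists (camera adjusted p = 0.963 and 0.383). With fry, which asks whether the genes of a list move on balance one way, adjusted p lay between 0.0188 and 0.0305 for these 4 lists and phosphate starvation. For fliF, flaG, atpG and atpA the adjusted p was 0.0543 to 0.0547 without planktonic replicate 2 and 0.0636 without planktonic replicate 3, and for fliF, atpG and atpA 0.0531 to 0.0584 without vented replicate 2. With only both groups in the fit it was 0.0558 for flaG and atpA and 0.0541 for atpG.

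In other lists some of the members moved. Of 41 genes for turnover of the second messenger cyclic di-GMP, 2 rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 0.000847, and 0.617 with an estimated correlation). The rises were in the GGDEF domain genes VF_A0476 (log2 4.52, SE 0.93) and VF_A0475 (log2 3.25, SE 0.72), and the fall was in the diguanylate cyclase gene VF_0094 (log2 -1.69, SE 0.39). Of 11 glycerol genes, glpD rose (log2 3.46, SE 0.83, 4 adjusted over the list alone). Of 20 nucleotide biosynthesis genes 3 rose (4 adjusted over the list alone), among them purM from 23.0 ± 8.04 to 134 ± 16.9 CPM (log2 2.54, SE 0.37) and pyrC (log2 1.93, SE 0.41), beside purF, named after its value was seen. For glycerol and nucleotide genes the camera adjusted p was 0.0249 and 0.0222, and 0.552 and 0.617 with an estimated correlation. In the list of the tricarboxylic acid and glyoxylate cycles, 4 of 10 genes fell (6 fell and 1 rose adjusted over the list alone). They were the succinyl-CoA synthetase genes sucC at -3.78 (SE 0.80) and sucD at -2.30 (SE 0.63), beside sucA and aceA, named after their values were seen. That list had a camera adjusted p of 0.0222, and 0.617 with an estimated correlation. By fry these 4 lists had adjusted p from 0.0188 to 0.0852. The camera call ended without vented replicate 1 for the tricarboxylic acid genes (0.066), without vented replicate 2 or 3 for nucleotide biosynthesis (0.057 and 0.0791) and without vented replicate 3 for glycerol (0.0947). The calls of VF_0094, VF_A0476, VF_A0475, glpD, pyrC, sucC and sucD each ended without planktonic replicate 2 (adjusted p 0.0554 to 0.119) and without planktonic replicate 3 (0.0636 to 0.11). Without vented replicate 2 those of VF_0094, VF_A0476, VF_A0475, pyrC, sucC and sucD ended (0.0523 to 0.109), without planktonic replicate 1 those of VF_A0475 (0.0551), glpD (0.07) and sucD (0.115), that of sucD also without vented replicate 1 (0.0588) or 3 (0.0902), and that of VF_0094 without vented replicate 3 (0.0502). With only both groups in the fit the adjusted p was 0.0911 for VF_0094, 0.0634 for VF_A0476, 0.0639 for VF_A0475 and glpD, 0.0541 for sucC and 0.0789 for sucD, and with library totals 0.0667 for VF_0094 and 0.0774 for sucD. With replicate as a further term it was 0.0568 for pyrC, 0.0596 for sucC, 0.065 for sucD and 0.0629 for VF_A0475 and VF_0094.

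Over all 3755 genes tested, 176 were higher and 211 lower in vented than in planktonic cells at an adjusted p below 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The libraries of both groups did not overlap for 1333 genes (35.5%, against 10% by chance). The total of 387 dropped to 45 without planktonic replicate 2, 26 without planktonic replicate 3, 89 without vented replicate 2 and 82 with only both groups in the fit, and rose to 565 without vented replicate 1 and to 862 with DESeq2. Deviations from the group means correlated at 0.132 to 0.182 between same-numbered planktonic and vented libraries, which may or may not be paired. With replicate as a further term 154 genes passed, 145 of them among the 387, and 24 of the 65 named calls ended. Of the 65 named genes, 16 passed whichever single planktonic or vented library was left out. SWT libraries, which share the fit, were not left out here. The 16 genes include luxA, fre_VF_A0918 and the acyl transferase VF_A0922 of luminescence, VF_1082, yghU_VF_1083, VF_1610, the pst genes, VF_A0487, VF_A1057, VF_A1087, purM, rpsE and rpsD. Scaling by library totals moved the median of all genes from -0.02 to 0.48 and the share of higher calls from 45.5 to 78.1%. Higher and lower calls numbered 65 and 24 without vented replicate 2, 279 and 162 without vented replicate 3, and 114 and 219 without planktonic replicate 1.

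Vented against SWT cells contrasted host-released bacteria with cells growing in rich broth. The luminescence genes rose here as well, in 8 of 8 (8 adjusted over the list alone, median log2 4.89, camera adjusted p = 3.23e-05, and 0.53 with an estimated correlation), with luxA up from 113 ± 15.8 to 3435 ± 2838 CPM (log2 4.92, SE 0.81, adjusted p = 0.00158). Genes for the breakdown of fatty acids rose in 5 of 7 (5 adjusted over the list alone, camera adjusted p = 1.99e-06, and 0.283 with an estimated correlation). The oxidation complex gene fadB went from 28.9 ± 12.7 to 5211 ± 2507 CPM (log2 7.49, SE 0.64) and fadA from 16.0 ± 3.86 to 2009 ± 1305 CPM (log2 6.97, SE 0.66), beside fadE, fadI and fadJ, named after their values were seen. The glyoxylate shunt genes aceB and aceA rose by 6.92 and 5.83, the second malate synthase VF_A0257 by 9.62 (SE 1.10), and the amino-acid-binding protein VF_1532 went from 3.18 ± 1.30 to 2436 ± 687 CPM (log2 9.55, SE 0.55, adjusted p = 1.66e-05).

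Of 17 genes of the symbiosis polysaccharide (syp) cluster, which is required for biofilm formation during colonization, 8 rose over SWT (10 adjusted over the list alone). The list had a camera adjusted p of 0.00429, and 0.318 with an estimated correlation. Levels stayed low, as in VF_A1028 with 0.959 ± 0.202 CPM in SWT and 19.7 ± 27.7 CPM in vented cells (log2 4.30, SE 1.09), whose adjusted p was 0.0503 without SWT replicate 2. Of 41 cyclic di-GMP genes 21 rose and 2 fell (21 and 3 adjusted over the list alone, camera adjusted p = 0.00114, and 0.53 with an estimated correlation). Among these VF_A0343 rose by 5.18 (SE 1.14). The falls were in VF_0094 (log2 -1.94) and VF_0596 (log2 -0.89), and the call of VF_0596 ended without SWT replicates 1, 2 and 3 (adjusted p 0.109, 0.0817 and 0.123) and vented replicates 2 and 3 (0.0586 and 0.119). With library totals the change in VF_0596 was only -0.11 (adjusted p = 0.824), and its adjusted p was 0.0594 with a minimum of 50 reads in 3 libraries and 0.0632 with only both groups in the fit. The copper and silver efflux genes VF_A0443 to VF_A0445 stood at 1886 ± 368, 1271 ± 496 and 1757 ± 801 CPM in vented cells and below 10 CPM in SWT. In planktonic cells VF_A0443 read 2743 CPM in replicate 1 and 0.767 and 1.76 CPM in replicates 2 and 3. The adjusted p of VF_A0443 was 0.0899, 0.0922 and 0.0838 without SWT replicates 1, 2 and 3, and 0.0519 and 0.0518 without vented replicates 2 and 3. VF_A0444 and VF_A0445 reached at most 0.0893 and 0.0748 without an SWT library, and VF_A0444 0.0501 without vented replicate 3.

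Genes of translation, ATP synthesis, fatty acid synthesis and replication fell from SWT to vented cells. Ribosomal protein genes fell in 37 of 56 (37 adjusted over the list alone, median -2.29) and all 7 ATP synthase genes fell (7 adjusted over the list alone, median -4.50), with atpA going from 11072 ± 1441 to 312 ± 166 CPM (log2 -5.15, SE 0.58). Aminoacyl-tRNA synthetase genes fell in 13 of 23 (13 adjusted over the list alone), fatty acid synthesis genes in 10 of 12 (11 adjusted over the list alone), and DNA replication and division genes in 11 of 24 with 1 rise (13 and 1 adjusted over the list alone), for example gyrB by 3.18 and parE by 2.94. The rise was in the primase gene dnaG (log2 1.10), with an adjusted p of 0.0846, 0.0935 and 0.063 without SWT replicates 2 and 3 and vented replicate 3, and 0.0525 with only both groups in the fit. Camera adjusted p was 1.55e-11, 1.83e-08, 0.000453, 0.00179 and 0.000843 for these 5 lists. With an estimated correlation the adjusted p was 0.283 for ATP synthase and 0.53 for the other 4. The list of the tricarboxylic acid and glyoxylate cycles fell in 8 of 10 genes, with sucC at -6.66 (SE 0.91). Its 2 rises were aceA and aceB of the glyoxylate shunt (8 and 2 adjusted over the list alone, camera adjusted p = 0.0285, and 0.53 with an estimated correlation). The camera call of that list ended without vented replicates 1, 2 or 3 (0.144, 0.0583 and 0.0511).

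Glycerol genes fell in 8 of 11 and sialic acid genes in 5 of 5 (8 and 5 adjusted over the list alone, camera adjusted p = 2.2e-05 and 0.000453, and 0.114 and 0.159 with an estimated correlation). The subunit genes glpA, glpB and glpC of the anaerobic glycerol-3-phosphate dehydrogenase had log2 changes of -7.32, -6.59 and -7.48, and the N-acetylneuraminate lyase VF_0663 went from 745 ± 129 to 37.8 ± 31.1 CPM. The other sialic acid genes were the transporter VF_0668 (log2 -4.03), and, named after their values were seen, nanQ and the synthase genes neuB and VF_0144, which make rather than use sialic acid. Of 53 flagellum and motor genes 23 fell and 3 rose (24 and 3 adjusted over the list alone, camera adjusted p = 2.56e-07, and 0.53 with an estimated correlation). Flagellin VF_1862 went from 13220 ± 4442 to 136 ± 98.9 CPM (log2 -6.60, SE 0.92). The 2 rises among the named genes were in flgA (log2 1.75) and in VF_A0186, annotated as a MotA2 motor protein (log2 2.88). The remaining rise was in VF_A0959, a diguanylate cyclase gene named after its value was seen. Fumarate reductase frdA fell from 5741 ± 4554 to 51.2 ± 15.0 CPM, and in a list of 36 genes for anaerobic respiration and fermentation 16 fell and 3 rose (16 and 3 adjusted over the list alone, camera adjusted p = 0.0181, and 0.53 with an estimated correlation, and 0.0774 without vented replicate 1). Its rises included torE (log2 3.73, SE 0.48) and the trimethylamine N-oxide reductase torA (log2 2.10, SE 0.49), beside torC, named after its value was seen. In the low-input libraries torE was likewise higher at 1 than at 1000 ng (log2 2.60, adjusted p = 0.0268).

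In all, 815 genes were higher and 654 lower in vented than in SWT cells by edgeR with Benjamini-Hochberg adjustment, of 3755 tested, and 1989 (53.0%, against 10% by chance) had libraries that did not overlap. Of 77 named genes 65 passed whichever single vented or SWT library was left out. Planktonic libraries were not left out here. Scaling by library totals moved the median of all genes from 0.10 to 0.84 and the share of higher calls from 55.5 to 79.0%. With fry, the lists named above had adjusted p from 0.000111 to 0.0248, except anaerobic respiration and fermentation at 0.0644. Of the lists called by camera but not named, that of plasmid pES100 (camera adjusted p = 0.0181) had 0.127 by fry. Nitrogen assimilation, amino acid biosynthesis and aerobic respiration had 0.000432 to 0.00584.

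**Figure D3:**
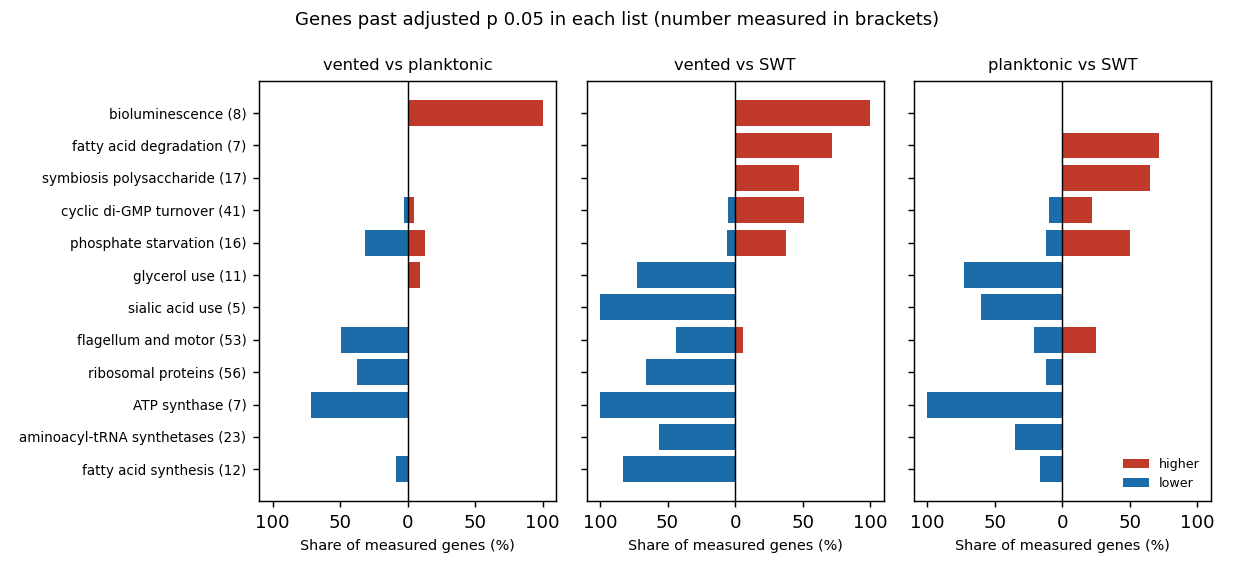
Share in percent (x axis) of the measured genes of 12 lists (y axis, number measured in brackets) that were higher (red, right) or lower (blue, left) at an adjusted p below 0.05 by edgeR, 1 panel per comparison. Luminescence genes were higher in 8 of 8 in both vented comparisons and in 0 of 8 in planktonic against SWT.

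Planktonic against SWT cells compared cells kept in seawater with cells growing in broth, between which medium, time and temperature (about 23 and 28 °C) differ together. Phosphate uptake was among the largest rises: VF_1610 went from 4.41 ± 3.16 to 9422 ± 3190 CPM (log2 11.02, SE 0.85, adjusted p = 3.17e-05), pstC rose by 9.98 (SE 0.78), VF_A0487 (OmpU2) by 10.49 (SE 0.79) and VF_A1087 by 10.44 (SE 0.76). Of 16 phosphate starvation genes 8 rose and 2 fell, both over all genes and adjusted over the list alone (camera adjusted p = 0.00351, and 0.693 with an estimated correlation). The falls were phoR (log2 -1.26, adjusted p = 0.0725, 0.0712, 0.0777 and 0.0613 without planktonic replicates 2 and 3 and SWT replicates 2 and 3) and the glycerol-3-phosphate transporter glpT (log2 -6.55). Fatty acid breakdown rose in 5 of 7 genes (5 adjusted over the list alone, camera adjusted p = 2.62e-05, and 0.268 with an estimated correlation), with fadA and fadB up by 6.72 and 6.62, beside fadE, fadI and fadJ, named after their values were seen. VF_1532 rose by 9.14 and the malate synthase VF_A0257 by 10.74 (SE 1.15).

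The syp cluster rose in 11 of 17 genes (12 adjusted over the list alone, camera adjusted p = 0.000729, and 0.268 with an estimated correlation), for example VF_A1029 from 0.503 ± 0.396 to 6.92 ± 1.13 CPM (log2 3.81, SE 0.98), whose adjusted p was 0.0554 without SWT replicate 3. No luminescence gene passed the test (median log2 -0.53, camera adjusted p = 0.569), and luxA stood at 113 ± 15.8 CPM in SWT and 57.9 ± 47.7 CPM in planktonic cells (adjusted p = 0.321). Without planktonic replicate 1, fre_VF_A0918 and VF_A0922 were lower in planktonic cells (log2 -1.56 and -1.61, adjusted p = 0.0341 and 0.0263).

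Glycerol use fell from SWT, whose broth holds glycerol, to planktonic cells in 8 of 11 genes (10 adjusted over the list alone, median -4.16). Its camera adjusted p was 4.42e-08 and, alone among the lists called in any of the 3 comparisons, it passed with an estimated correlation (adjusted p = 0.0296). Here glpA went from 2459 ± 1520 to 4.41 ± 0.876 CPM (log2 -9.12, SE 0.76), and glpB, glpC and the glycerophosphoryl diester phosphodiesterase VF_A0958 had log2 changes of -9.06, -8.08 and -7.17 (SE 0.42 for the last). Sialic acid genes fell in 3 of 5 (3 adjusted over the list alone, camera adjusted p = 0.0011, and 0.172 with an estimated correlation), with the transporter VF_0668 at -5.57 (SE 0.50) and the lyase VF_0663 at -4.66 (SE 0.88), beside nanQ, named after its value was seen. All 7 ATP synthase genes fell (7 adjusted over the list alone, camera adjusted p = 0.000729, and 0.587 with an estimated correlation), with atpD at -2.76 (SE 0.54) and atpA at -2.51 (SE 0.51). Nucleotide biosynthesis genes fell in 7 of 20 (7 adjusted over the list alone, camera adjusted p = 0.00584, and 0.886 with an estimated correlation), with purL at -2.71 (SE 0.37). Outside the lists the glycine cleavage gene gcvH fell from 772 ± 250 to 7.06 ± 1.21 CPM (log2 -6.77, SE 0.46) and the formate transporter gene focA_VF_A0386 from 839 ± 533 to 7.13 ± 3.62 CPM (log2 -6.88, SE 0.90).

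By edgeR with Benjamini-Hochberg adjustment 644 genes were higher and 503 lower in planktonic than in SWT cells, of 3755 tested, and 2139 (57%, against 10% by chance) had libraries that did not overlap. By fry the lists named above, luminescence aside, had adjusted p from 8.48e-05 to 0.0226. Camera also called aminoacyl-tRNA synthetase, amino acid biosynthesis, and DNA replication and division genes as lower (adjusted p = 0.00451, 0.0341 and 0.0143). For each of them it was 0.951 with an estimated correlation. By fry these lists had adjusted p of 0.103, 0.0587 and 0.0486. The total of 1147 dropped to 744 without SWT replicate 3, and rose to 1491 with DESeq2 and 1682 with only both groups in the fit. Scaling by library totals moved the median of all genes from -0.01 to 0.22 and the share of higher calls from 56.1 to 65.4%.

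Genes that set vented cells apart from both free-living states numbered 206, with 96 higher and 110 lower than in either. Among those higher were all 8 luminescence genes, VF_1082, yghU_VF_1083, the lipoprotein VF_A0622 (log2 4.99 over planktonic, SE 0.76) and its neighbour VF_A0623 of unknown function (0.425 ± 0.737, 0.746 ± 0.626 and 178 ± 147 CPM in SWT, planktonic and vented cells). Among those lower were flaG, flagellin VF_2079, motX of the flagellar motor, sucC, and the ribosomal protein genes rpsE, rpmD, rpsK and rpsD. Against planktonic cells motX, VF_2079 and rpmD reached an adjusted p of 0.126, 0.108 and 0.136 without planktonic replicates 2 or 3, and 0.0889, 0.0755 and 0.107 without vented replicate 2, while VF_A0622 and VF_A0623 reached 0.0636 and 0.0644 without planktonic replicate 3. That of rpsK was 0.0547, 0.0639 and 0.0531 without planktonic replicates 2 and 3 and vented replicate 2. Those of motX and VF_2079 were 0.0616 and 0.0593 without vented replicate 3. The call of rpmD against planktonic cells ended in 5 of the fits that left out 1 library. With only both groups in the fit those of motX, VF_2079, rpmD, rpsK, flaG and sucC were 0.11, 0.0922, 0.114, 0.0558, 0.0558 and 0.0541, and that of rpmD was 0.0576 with replicate as a further term. Another 44 genes moved in opposite directions against planktonic and SWT. If both lists of calls were independent, 38.2 shared rises and 36.8 shared falls would be met. In 20 simulations that drew all 9 libraries, vented ones included, from 1 common mean per gene, 0 genes were called in both. With no group changed, hardly any call could arise. These simulations therefore cannot show how much of the overlap comes from sharing the vented libraries. Across genes the covariance of both sets of log2 fold changes was 1.16, against 0.212 in simulations, with correlations of 0.430 and 0.508. The vented libraries were too few to split, so part of the excess may come from sharing them. The 206 dropped to 30 without planktonic replicate 2, 15 without planktonic replicate 3, 100 without SWT replicate 2, 101 without SWT replicate 3 58 without vented replicate 2 and 102 with replicate as a further term, and rose to 458 with DESeq2. Their balance was not stable: 296 were higher and 74 lower with library totals, 48 and 10 without vented replicate 2, 168 and 93 without vented replicate 3, and 74 and 126 without planktonic replicate 1.

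Chromosome II is the smaller chromosome and carries the luminescence and syp clusters. In vented against SWT cells 361 of its genes were higher and 107 lower of 1138 tested, with a median log2 fold change of 0.84. On chromosome I 452 were higher and 534 lower of 2564, with a median of -0.17. On plasmid pES100 2 were higher and 13 lower of 53, with a median of -1.04. In planktonic against SWT cells 230 chromosome II genes were higher and 136 lower, and on chromosome I 409 and 365. Whether these shares differ between the chromosomes was not tested. Against planktonic cells the vented medians were -0.14 for chromosome I, 0.34 for chromosome II and -0.53 for the plasmid. These medians are relative to all genes, whose own median was 0.10 against SWT and -0.02 against planktonic cells and became 0.84 and 0.48 with library totals.

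The low-input libraries came from broth-grown cells and asked what library preparation does to the counts. Without depletion rRNA took 90.6% ± 0.477 (SD, n = 3) of CDS plus rRNA reads. With it the share was 1.12% ± 1.93 (n = 8, median 0.439%), and each depleted library lay below each undepleted one (difference 89.4 percentage points, exact two-sided permutation p = 0.00606 over 165 arrangements). With only the 1000 and 500 ng inputs, 2 against 2 libraries, the exact p was 0.333, the smallest that design can give.

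Protein-coding genes also differed between depleted and undepleted libraries, mostly by small factors. At 1000 and 500 ng 510 genes were higher and 535 lower after depletion (edgeR with Benjamini-Hochberg adjustment, 3598 tested). Of these, 15 and 58 moved by at least 1 on the log2 scale. Across genes the 4 libraries correlated at 0.9954 and 0.9966 within and 0.9847 to 0.9924 between the arms. The undepleted 100 ng library was not in that test. It correlated at 0.9955 and 0.994 with the depleted 1000 and 500 ng libraries, and at 0.9907 and 0.9957 with the undepleted ones. Differences between undepleted libraries may thus account for part of the calls. Ribosomal protein genes rpmF and rpsG were higher by 1.46 (SE 0.17) and 1.17 (SE 0.13), and the acyl carrier protein VF_0847 by 1.11 (SE 0.13). The hypothetical genes VF_0171 and VF_0173 were lower by -2.67 (SE 0.21) and -2.12 (SE 0.34), and VF_0916 by -2.05 (SE 0.14). Of 56 ribosomal protein genes 29 were higher and 5 lower, and of 8 luminescence genes 6 were lower (median -0.52). Camera adjusted p was 8.98e-11 and 0.00134, and 0.918 for both with an estimated correlation. The total of 1045 dropped to 465 with all 3 undepleted libraries against depleted ones of 25 ng or more, where VF_0847 and VF_0173 changed by 0.63 and -0.39 (adjusted p = 0.0717 and 0.688). With DESeq2 the adjusted p of VF_0173 was 0.0667. With 1 library left out, an alternative chosen after the data were seen in which the lone library of an arm is assumed to vary like the others, it was 1756 without the undepleted 500 ng library, 552 without the depleted 1000 ng library and 451 without the depleted 500 ng library.

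No gene passed the test between 15 and 17 PCR cycles at matched inputs of 5, 2.5 and 1 ng (0 of 3326 by edgeR and 0 by DESeq2, with 83 at an unadjusted p below 0.05 by edgeR and 103 by DESeq2). In simulated counts this test recovered 37.3% of 2-fold changes. Along the input series from 1000 to 1 ng, 52 genes rose and 53 fell with increasing input (edgeR, Benjamini-Hochberg, 2922 tested). The hypothetical gene VF_2550 was 13.6-fold higher at 1000 than at 1 ng in the fit (0.38 log2 units per doubling of input, SE 0.03), and torE was 6.07-fold higher at 1 ng (-0.26 per doubling, SE 0.06), as were tcpA (4.93-fold) and VF_2571, subunit I of the ATP synthase (4.01-fold). The adjusted p of torE was 0.136, 0.148, 0.0508 and 0.0995 without the 1000, 500, 50 and 1 ng libraries, and that of tcpA 0.0971 and 0.13 without those of 1000 and 500 ng. The total of 105 fell to 9 without the 1000 ng library, 11 without that of 500 ng, 68 without that of 5 ng and 35 without that of 2.5 ng, and was 182 without that of 10 ng and 294 with DESeq2.

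The number of genes detected at equal depth fell from 2851 at 1000 ng to 2601 at 1 ng (Pearson r with log10 input 0.900, n = 8, exact permutation p = 0.00141, adjusted 0.00707 over 5 relations; Spearman rho 0.929, exact p = 0.00223; r = 0.887 without the 2 inputs farthest from the median). The aligned share fell from 99.0% at 1000 ng to 36.6% (36.5 to 36.6) at 1 ng (r = 0.871, exact p = 0.00593, adjusted 0.0148; rho 0.976, exact p = 3.97e-04; r = 0.974 without the 2 farthest). The correlation across genes with the 1000 ng library fell from 0.997 at 500 ng to 0.933 at 1 ng (r = 0.853, n = 7, exact p = 0.0133, adjusted 0.0222; rho 0.893, exact p = 0.0123; r = 0.751 without the 2 farthest). The rRNA share (r = 0.0324, exact p = 0.940; rho 0.143, exact p = 0.752) and the CDS reads (r = 0.359, exact p = 0.397; rho 0.548, exact p = 0.171) gave no relation that passed.

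**Figure D4:**
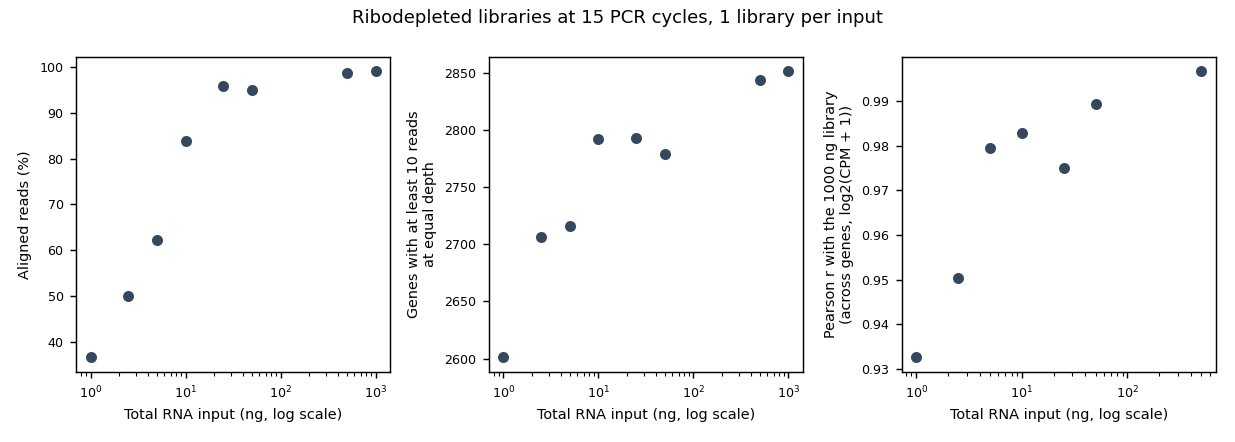
Aligned reads in percent, genes with at least 10 reads at equal depth, and Pearson r across genes with the 1000 ng library (y axes) against total RNA input in ng (x axes, log scale). Each point is 1 ribodepleted library at 15 cycles. Genes detected fell from 2851 to 2601 between 1000 and 1 ng.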

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

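Of the tests below, those of host reads, of small input for ribosomal proteins, and of flagellar and ribosomal genes without vented replicate 1 were chosen only after the result was seen, and so were the use of a spread over deciles and the splits that part pairs for distinct genes. No biological explanation was tested for vented replicate 1 or for the low-input libraries, since the design names none.

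Among the 8 ribodepleted libraries at 15 cycles, that of 25 ng held 5.861% rRNA (95% Wilson interval 5.82 to 5.90), far from the others with a median of 0.417%. The gap to the nearest library was 0.870 of the whole range; chance alone marks about 1 in 20 such groups. Reads that aligned to nothing in the genome made up 74.87% of the vented reads against 2.665% in SWT. Aligned reads outside protein-coding and rRNA genes made up 27.11% of the aligned reads in planktonic and 23.67% in vented libraries, against 12.88% in SWT.

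Vented replicate 1 stood apart, with r = 0.665 and 0.664 against vented replicates 2 and 3 across genes. Lower depth as the whole cause is argued against: thinned to the same 687894 reads, replicates 2 and 3 still correlated at 0.9548 with each other and 0.694 with replicate 1, which had 542 genes without a read against 77 and 121. Host reads that misalign are argued against by the pair of replicates 2 and 3, which correlated at 0.9703 although replicate 2 aligned only 19.0% of its reads. Random loss of molecules in a low-yield library stays open, because neighbouring genes' log2 ratios correlated at 0.1591, between the 0.03514 of the 1 ng library and the 0.4542 and 0.5641 of planktonic and SWT replicate 1. In addition 134 genes had 0 reads where at least 20 were due, against 6 in the 1 ng library, and the neighbour correlation between vented replicates 2 and 3 was 0.279.

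Flagellar and ribosomal protein genes lay lower in vented than in planktonic cells (list medians -2.24 and -1.50). Small total RNA input as the cause is argued against by the low-input series of broth-grown cells. In it ribosomal protein genes shifted from 1000 to 1 ng by a median of 0.2225 (SE 0.0828) and flagellar genes by 0.1563 (SE 0.0868), upward and not downward. Both SEs treat genes as independent and leave out the spread between libraries, of which each input had 1. The series varied only the amount of RNA from broth-grown cells, whereas 74.87% of vented reads did not align to the genome. Little V. fischeri RNA among RNA of another source was therefore not tested as a cause. Replicate 1 alone as the cause is argued against by the medians without it, -1.303 for ribosomal protein genes (camera adjusted p = 9.68e-11) and -1.884 for flagellar genes (camera adjusted p = 1.47e-17). With all libraries both lists had an adjusted p = 0.552 with an estimated correlation, and across 2922 genes the vented to planktonic change correlated at -0.0607 with the change over input. A difference between host and seawater was not tested and stays open, since the host, the time of day, the light and the collection steps differ together.

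Chromosome II genes lay above chromosome I genes in vented against SWT cells by a median difference of 1.00 on the log2 scale (1.005). Lower expression of chromosome II genes stays open: within deciles of mean CPM the difference was 0.8334 on average, but with a standard error of 0.2608 over deciles, a range of 0.0484 to 3.10, and a mean of 0.581 without the largest. Replicate 1 as the whole cause is argued against by a difference of 0.8533 without it (SE 0.08568). That SE treats genes as independent and leaves out the spread between libraries. Small total RNA input is argued against by a difference of -0.05038 between 1000 and 1 ng. This holds only for RNA of broth-grown cells, with 1 library per input. Gene dosage stays open: along chromosome I the fold change rose with distance from the start of the locus numbering, near dnaA (rho 0.1936 over 2466 genes, reached by 0.0130 of circular shifts). More copies near the replication origin in fast-growing SWT cells may contribute, but would not alone give the rho of 0.151 and the chromosome difference of 0.475 between vented and planktonic cells (0.114 and 0.402 in planktonic against SWT), and regulation was not tested.

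With 3 against 3 libraries, 10 splits are possible, too few for a share under 0.05. For vented against planktonic the 3 other splits that part all 3 same-numbered pairs, as the real one does, gave 0 genes and at most 8 lists; those that part 1 pair gave up to 1 gene and 16 lists. The real split gave 387 genes for vented against planktonic and the highest other split 1; for vented against SWT these were 1469 and 0, and for planktonic against SWT 1147 and 0. For lists called by camera the real and highest other values were 20 and 16, 18 and 24, and 10 and 17; 1, 4 and 6 of the 10 splits called as many. For PCR cycles the real split gave 0 genes, which all 10 splits must reach, so their count decides nothing. The highest other value, 269, came from 2 splits that part only the 1 ng pair and so set 1 library against 1. It shows no more than that this pair was the least alike (r = 0.897, against 0.974 at 5 ng and 0.952 at 2.5 ng). Of 100 drawn splits of the 840 possible for genes distinct in vented, 1 (the real one) gave 206 and the highest other 127. Also run were all 80 splits whose vented group holds 1 library of each same-numbered planktonic and vented pair. Of these, 1 (the real one) gave 206 and the highest other 127. That other split keeps the 3 real groups and takes planktonic as the distinct one. SWT cannot be the distinct group in any of the 80. Splits that mix the groups widen the spread within them, so a count above theirs shows only that the groups differ. These splits cannot decide whether the number of genes distinct in vented exceeds chance.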

How the results depend on the processing

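No test in this part was chosen after the result was seen except leaving out a library in the ribodepletion test and thinning in the input profile. Directions of all named genes that passed the main test held under each alternative run in which they were tested. The luminescence genes in planktonic against SWT, none of which passed, were not checked for direction. Genes changed between vented and planktonic cells numbered 387, and 603 with library totals, 862 with DESeq2, 82 with only both groups in the fit, and 26 to 565 leaving out 1 library, of which 26 and 350 were among the 387. Genes distinct in vented numbered 206, and 370 with library totals, 458 with DESeq2 and 15 to 307 leaving out 1 library. For planktonic against SWT leaving out 1 library gave 744 to 987 against 1147, DESeq2 gave 1491 and only both groups in the fit 1682. Vented against SWT stayed within 1.5 times of 1469 under every alternative (991 to 1801 leaving out 1 library). The replicate numbers may pair planktonic with vented libraries, though no label states it. There a replicate block gave 154 genes and 102 distinct genes. It ended 24 of 65 named calls and 1 of 20 list calls (fatty acid synthesis, camera adjusted p = 0.062). Between SWT and either group no library correlated best with its own number. The block gave 1237 and 999 genes for vented and planktonic against SWT. Against SWT it ended 7 of 77 named calls in vented cells. In planktonic cells it ended 2 of 36 named calls and 1 list call (amino acid biosynthesis, camera adjusted p = 0.0528). With an estimated correlation the lists called were 0, 0 and 1 instead of 20, 18 and 10. With fry they were 11, 31 and 11, of which only 9, 16 and 8 were among the camera calls. Vented against planktonic gave 11 to 19 lists by camera leaving out 1 library. Ribodepletion gave 465 genes instead of 1045 with all 3 undepleted libraries against 25 ng or more, and 451 to 1756 leaving out 1 library. The rRNA difference was 89.91 with only 1000 and 500 ng, where 2 against 2 libraries cannot pass, and 89.18 to 89.65 leaving out 1 undepleted library. Genes changed with input numbered 105, 294 with DESeq2 and 9 to 182 leaving out 1 library. PCR cycles gave 0 in each alternative, and the relation of the profile with input stayed at 0.853 to 0.876. Calls of single named genes were lost 230 times over all alternatives for vented against planktonic, 55 for vented against SWT, 25 for planktonic against SWT (2 gained), 22 for input and 5 for ribodepletion. Leaving out a library or a group removes residual degrees of freedom, which would not by itself raise a count. Without vented replicate 1 the count for vented against planktonic rose to 565. There edgeR's common coefficient of variation between libraries of a group was 0.396, against 0.509 with all 9 libraries. Beyond that the cause was not tested. Depth limits genes with few reads most in vented replicate 1, with 687894 CDS reads.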

Other observations

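The tests in this part use lists fixed beforehand; the members named were chosen after their values were seen, and the alternatives were not run for them. The sigma factor gene rpoS, which directs the general stress response, went from 97.5 ± 55.4 CPM (SD, n = 3) in SWT to 5401 ± 1801 in planktonic and 4460 ± 2143 in vented cells (log2 5.79 and 5.52 by edgeR with Benjamini-Hochberg adjustment, adjusted p = 2.7e-04 and 3.5e-04), and rmf, the ribosome modulation factor, from 561 ± 327 to 6694 ± 67.8 and 3277 ± 1162 CPM (log2 3.58 and 2.55). Both are on the list of starvation and ribosome hibernation. Of its 14 genes 5 rose and 1 fell in planktonic cells (5 and 3 adjusted over the list alone, camera adjusted p = 0.176, fry 0.103), and 4 rose and 3 fell in vented cells (5 and 3 adjusted over the list alone, camera adjusted p = 0.544, fry 0.341), so the list as a whole did not pass. Among the falls, hpf_VF_0562 went from 9724 ± 5209 CPM in SWT to 963 ± 309 CPM in vented cells (log2 -3.34).

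Of 8 quorum sensing regulators 4 rose in vented over SWT cells (4 adjusted over the list alone, camera adjusted p = 0.18, and 0.53 with an estimated correlation, fry 0.0234): ainR (log2 2.95), the C8-HSL synthase gene ainS (14.2 ± 2.13 to 91.5 ± 32.6 CPM, log2 2.68), and the genes VF_0708 (LuxQ, log2 1.85) and VF_0938 (LuxU, log2 2.05). Both ain genes rose in planktonic over SWT cells too (log2 2.63 and 2.16), and neither passed between vented and planktonic cells (adjusted p = 0.70 and 0.61). The regulator gene VF_2177 (LitR) stood at 1018 ± 310, 937 ± 231 and 779 ± 264 CPM in SWT, planktonic and vented cells. Of 9 nitric oxide genes 4 rose and 1 fell in vented over SWT cells (4 and 1 adjusted over the list alone, camera adjusted p = 0.251, and 0.53 with an estimated correlation, fry 0.00834), with hnoX, for a heme sensor of nitric oxide, at 11.7 ± 5.12 CPM in SWT, 179 ± 96.4 in planktonic and 207 ± 60.4 in vented cells, while the dioxygenase gene hmpA fell (log2 -1.78). In the porin list, VF_1162 (TolC) rose in vented cells from 34.8 ± 11.1 CPM in planktonic to 547 ± 409 CPM (log2 3.97, adjusted p = 0.0069), and ompU stood at 8733 ± 1022, 1552 ± 206 and 4978 ± 3073 CPM in SWT, planktonic and vented cells. Of 17 porin genes 1 rose and 1 fell from planktonic to vented cells (3 and 1 adjusted over the list alone). The list did not pass there (camera adjusted p = 0.394, fry 0.293).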
